A study of Homo sapiens with 7 samples.

How the data were processed

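The series holds 4 ChIP libraries made with an antibody to TCF21 and 3 input DNA libraries, all from NCI-H295R cells. Per the labels' protocols, cells were plated 24 h before transfection with pCMVMycPOD1 and kept for 48 h after it, in medium with 2% serum. Chromatin (100 µl) was sheared with 6 pulses of 10 s at 25% amplitude, and library fragments were 250 bases on average. For the ChIP libraries, chromatin was precipitated with 5 µg of antibody and libraries were made from 7 ng of DNA. No DNA amount was recorded here for the input libraries. Groups were taken from the antibody label. The labels do not say whether libraries came from separate cultures.

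Per the series design text and the submitters' processing notes, reads were mapped to GRCh38, with BWA 0.7.13, SAMtools 1.8, FastQC 0.11.7 and bedtools among the named tools. Base quality was checked against a Phred score of 30, low-quality and duplicate reads were removed, peaks were called with MACS2 2.1.1 at p under 0.01 within the AQUAS pipeline, peaks were kept at an IDR under 0.05, and ENCODE blacklist regions were excluded. The blacklist was not available here, so whether the listed regions overlap it was not checked. The design text speaks of 2 replicates while the labels list 4 ChIP and 3 input libraries. Which of them entered the merged list and were compared for the IDR, and how reads with several equally good positions were handled, is not given in the sources used here.

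Only 1 table was used, a merged and annotated list of 70 regions whose title gives a larger number. Whether the 70 are the whole list is not known here, and results hold for the listed regions. Regions were neither called per sample here nor could they be compared between samples. The deposited score of each region lies between 543 and 1000 and follows the scale of the IDR tool, on which an IDR of 0.05 gives 540 and 1000 is the ceiling. The authors' fold at the summit, −log10 p and −log10 q had lost their decimal mark in 66, 70 and 34 of 70 cells, so as deposited these columns are digit strings with the unit of a score. The mark was put back after the first digit, or after 2 digits where a −log10 p had 7. After this, 0 of 2415 pairs of regions were ordered differently by p and by q, against 324 pairs as deposited. This check tests p and q, while the folds rest on the rule alone. Positions, summit offsets and distances are plain coordinates, the unit "other", per the file headers. Start positions counted from 0 and are given here from 1.

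The reference was GRCh38 with GENCODE release 44 (62663 genes, 20033 of them protein-coding) and RefSeq positions of the 45S genes. As a check of the build, 51 of 61 transcript start distances the authors gave for regions inside genes matched GENCODE within 1 base. Of the authors' transcript entries, 26 were missing from that release. For 19 of 19 regions placed downstream of a gene, the authors' distance from the transcription start repeated the distance from the gene, so it was not used as a distance from the start.

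Annotation classes and distances were taken at the region centre and compared with 200000 random positions outside assembly gaps, with the regions' own chromosome shares, by two-sided exact binomial tests with Benjamini-Hochberg adjustment over 4 classes, 9 gene lists (235 genes) or 24 chromosomes. Sequence patterns were counted on both strands in the central 200 bases and in windows 2 kb to each side, and tested by an exact sign test of the centre count against the mean flank count, adjusted over 9 patterns. That sign test turned out to be biased towards fewer sites in the centre, because the mean of 2 flanks exceeds 0 more often than 1 window does. With 10 background windows per region, as in the comparison with GC-matched windows, the bias is severe. A two-sided permutation of windows within each region (100000 permutations) was therefore added after the data were seen, and for most patterns the report describes its p is printed beside that of the sign test. The share of regions with more E-boxes in the centre was also set against its values in 10000 such permutations. For the motif comparisons under other settings, the value recorded was changed after the first results from the share of regions with the higher count in the centre to the share with a site. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only. The limit of a share of 0 is 3 of the 70 regions, a one-sided limit below the upper end of the two-sided interval.

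Copies were counted as the share of 32-base words of a region found 2 or more times in the reference without alternate contigs, and compared with 20 random windows per region of the same width and chromosome by Fisher's exact test. A base was called tandem repeat when it lay in a stretch of at least 20 bases, and at least 1 period, that matched the sequence 1 to 60 bases before it at 80% or more. Word copies inside a tandem repeat also count as copies, so both measures overlap. Both were chosen after the sequences of the regions had been looked at. In the ribosomal DNA spacers, E-boxes and tandem repeats were compared with the rest of the spacer by 10000 rotations of the region positions.

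The tests were tested on simulated data. Of 100 draws of 70 random regions, 4 were called for promoters and 4 for distance to a start at p under 0.05. For CANNTG in random windows the sign test called 6 of 50 draws and the permutation 1 of 50, and for CAGCTG they called 6 and 2 of 50. With CAGCTG planted in 35 of 70 windows, the sign test recovered 50 of 50 draws at an adjusted p under 0.05. Recovery by the permutation, or with fewer planted sites, was not recorded. The draws were of random positions, so they do not give the error rate for clustered or repeat-rich regions. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9 were used.

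The groups, tests, gene lists, patterns and a first set of alternatives were fixed before the data were examined. These alternatives were the 35 regions ranked highest by score, a promoter window of 3 kb, class by any overlap of at least 1 base, protein-coding genes only, windows of 1 and 50 kb around a start, whole regions, flanks at 10 kb, GC-matched windows in 5% bins, the authors' gene, genes within 50 kb, and main chromosomes only. Added later were the sets without ribosomal DNA spacer regions and with q under 0.05, windows on the summit, the permutation, the set without the spacers against GC-matched windows, and the settings of both repeat measures. Genes named were those of the 20 regions ranked highest by score with ties by position, of the 10 ranked highest within 1 kb of a start, of fixed lists other than the long-gene control, and the 5 genes with most regions, of which 4 had more than 1. Because all other genes tie at 1 region, the fifth was not singled out. PRR20E, LCE5A and the genes of regions outside both repeat classes, in the closing section, were chosen after their values were seen. One gene that this rule names is not reported here.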

Results

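Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out for TCF21, a basic helix-loop-helix transcription factor also called POD1, in NCI-H295R cells. NCI-H295R is a steroid-producing line from a human adrenocortical carcinoma, and these cells had been transfected with a plasmid, pCMVMycPOD1, labelled as an overexpression vector. The 7 samples comprised 4 TCF21 ChIP libraries, prepared with an antibody to TCF21, and 3 input DNA libraries prepared without immunoprecipitation. The series title states its purpose, the search for TCF21 targets in adrenocortical carcinoma cells. The table used here lists 70 regions of GRCh38 that the authors kept at an irreproducible discovery rate (IDR) under 0.05. The title of the table gives a larger number of regions, so these may be part of a longer list, and every share, test and count of 0 below holds for the 70 listed regions alone. The table holds 1 merged value per region and none per library. ChIP therefore could not be set against input, replicates could not be compared, and the read depth behind each region is unknown. Scores, folds at the summit, p-values and q-values per region are the authors' and are used to describe, rank, filter or compare regions within this list only.

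The first question was which parts of the genome the regions covered. A block of 18 regions lay on the short arm of chromosome 21, in the spacers between the genes of 45S ribosomal RNA, the precursor of the 18S, 5.8S and 28S rRNAs. Among the 20 regions ranked highest by the authors' score, 10 lay in these spacers. The other 10 included regions annotated by the authors to FMN2, TCF21, CNTNAP2, CACNA1B, TUBA3C, PRDM7, PTPRN2, BDH1 and ADGRA1. Apart from KCNE1B, named for 18 regions, the genes named most often were CWH43 with 3 regions and OR11H1, an olfactory receptor gene, and PTPRN2, of the receptor-type tyrosine phosphatase family, with 2 each. By the authors' distances, the CWH43 regions lay 224216 to 260700 bases past the end of that gene. The OR11H1 regions lay 4501498 and 4462467 bases upstream of OR11H1, while both PTPRN2 regions lay inside PTPRN2. For the 70 regions the authors' table named 49 genes, of which 45 were named once.

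The region with the largest fold at the summit, 6.70, lay on chromosome 16 at 90116724 to 90117592, and its centre was 25085 bases from the nearest GENCODE start of PRDM7, which encodes a PR/SET domain protein (39401 bases upstream of the gene in the authors' table). A fold of 6.57 and a −log10 q of 4.91 belonged to a region in an intron of CNTNAP2, a neurexin-family adhesion gene, on chromosome 7 at 148331526 to 148331804. The region assigned to CACNA1B, the N-type calcium channel subunit, had a fold of 6.41 on chromosome 9 at 138231359 to 138232392, 106735 bases past the end of the gene by the authors' distance. An intronic region of FMN2, which encodes an actin-nucleating formin, lay on chromosome 1 at 240184890 to 240185126 and had a fold of 4.99. The region assigned to TUBA3C, an alpha-tubulin gene, had a fold of 5.23 and lay 35358 bases past the end of the gene by the authors' distance. A region in an intron of ADGRA1, an adhesion G protein-coupled receptor gene, also had a fold of 5.23. The higher-ranked PTPRN2 region had a fold of 5.59, and the region that the authors' table placed 50017 bases past the end of BDH1, a ketone-body dehydrogenase gene, had a fold of 4.73.

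Over all 70 regions the median width was 271 bases (163 to 2680) and the median fold was 3.77 (2.29 to 6.70). The q-value was under 0.05 for 27 regions (38.6%, exact 95% interval 27.2 to 51.0) and 0.05 or more for 43. The same −log10 p of 4.63 was shared by 18 regions, 0 of them in the spacers. Chromosome 21 held 19 regions where its length predicted 0.955 (27.1%, exact 95% interval 17.2 to 39.1, two-sided exact binomial test, adjusted p = 2.9e-18 over 24 chromosomes). Without the spacer regions it held 1 against 0.710 expected (exact binomial test, adjusted p = 0.925). Neighbouring regions and copies of one repeat are not independent, so p-values over regions are too small to the extent that regions share a cause.

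The ribosomal DNA regions ran from position 8203273 to position 8465405 of chromosome 21. Of these, 7 followed RNA45SN2, 7 followed RNA45SN3, 3 followed RNA45SN1 and 1 preceded RNA45SN2. None overlapped a 45S gene (0 of 18 regions). Of the 17 that followed a 45S gene, 13 had a counterpart in another spacer within 500 bases of the same distance from the gene end. Regions 28167 and 28131 bases past the ends of RNA45SN2 and RNA45SN3 had folds of 5.31 and 3.50, and those 5847 and 5835 bases past them had folds of 3.39 and 3.49. The authors' table assigned all 18 to KCNE1B and gave distances of 373347 to 634111 bases from it. GENCODE release 44 places KCNE1B at 7816677 to 7829632, which differs slightly from the gene end behind those distances. That release labels KCNE1B an artifact copy of KCNE1, a potassium channel subunit gene.

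The spacer regions included 9 of the 14 regions with the top score of 1000. Their q-value was under 0.05 in 15 of 18 (83.3%, exact 95% interval 58.6 to 96.4), against 12 of 52 elsewhere (23.1%, 12.5 to 36.8; two-sided Fisher's exact test, p = 9.8e-06). The spacer regions nevertheless had a lower median fold (3.57 against 4.04 elsewhere) and a larger median width (516.5 against 257 bases). Tandem repeats covered 93.0% of their bases and 12.1% of the rest of the spacer, and pyrimidines made up 86.6% of their bases against 54.4%.

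**Figure D1:**
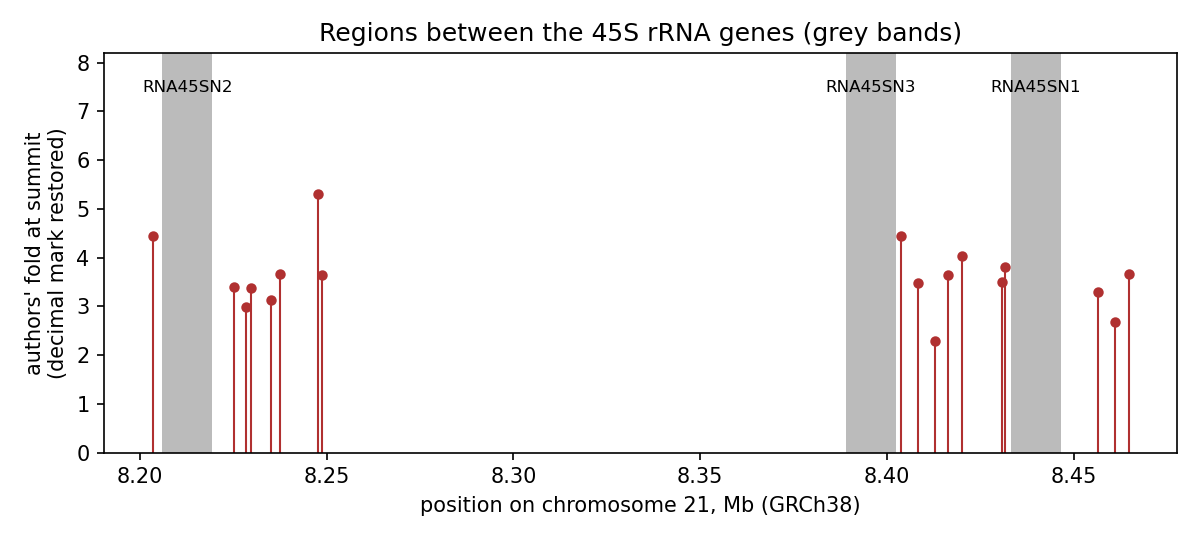
The 18 regions on the short arm of chromosome 21 by position in Mb (horizontal axis) and the authors' fold at the summit with the decimal mark restored (vertical axis); grey bands are the 45S genes RNA45SN2, RNA45SN3 and RNA45SN1. Each line ends in a point at the fold of 1 region, from 2.29 to 5.31, and all points lie outside the grey bands.

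Outside the spacers, tandem repeats with periods up to 60 bases made up most of the sequence in 24 of 52 regions (46.2%, exact 95% interval 32.2 to 60.5), against 1.15% of random windows of the same widths and chromosomes (Fisher's exact test, p = 3.8e-26). Over 90% of bases were tandem repeat in 28.8% of regions against 0.385% of windows. Of the 10 top-ranked regions elsewhere, 7 were over 50% tandem repeat, among them those of FMN2, CNTNAP2, TUBA3C, PTPRN2, BDH1 and ADGRA1. With periods up to 200 bases the number was 28 of 52, which adds the regions of PRDM7, CACNA1B and SCGB1C2 and 1 of the 3 of CWH43. Most 32-base words occurred 2 or more times in the genome in 39 of 52 regions (75.0%, 61.1 to 86.0), against 15.2% of random windows (Fisher's exact test, p = 2.8e-20). Over 90% of words were multi-copy in 32.7% against 8.17%. Both measures were chosen after the data were seen.

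**Figure D2:**
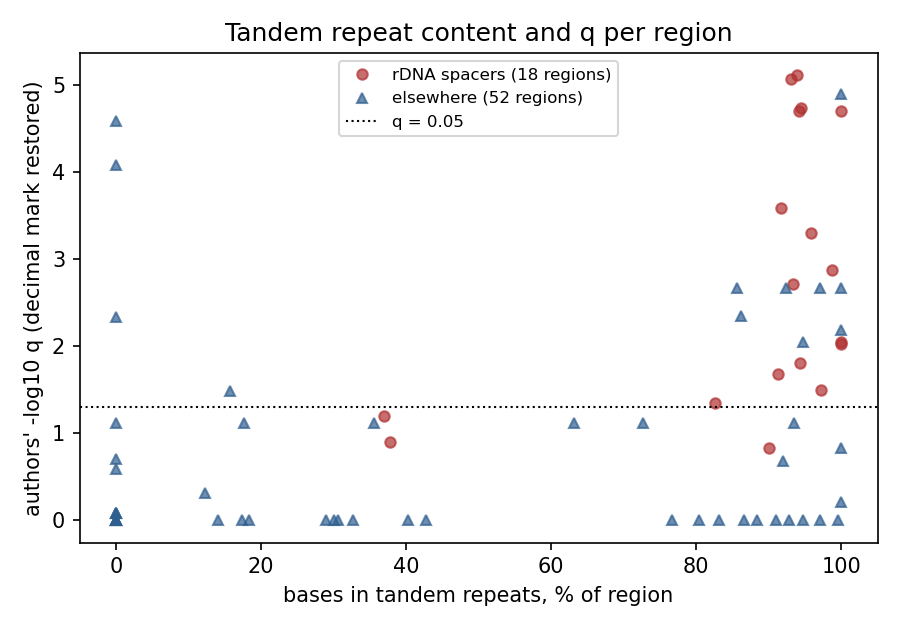
Percent of each region's bases in tandem repeats with periods up to 60 bases (horizontal axis) and the authors' −log10 q with the decimal mark restored (vertical axis), for 18 regions in the ribosomal DNA spacers (circles) and 52 elsewhere (triangles); the dotted line is q = 0.05. Above the line lie 15 of the spacer regions and 12 of the others.

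The next question was whether regions lay at genes and promoters. Of the 70 regions, 12 had their centre within 1 kb of an annotated transcription start (17.1%, exact 95% interval 9.18 to 28.0), against 7.47% of random positions (exact binomial test, adjusted p = 0.022). Of the 12, 6 lay in the ribosomal DNA spacers, near starts of small or unnamed RNA genes. Those near the start of a protein-coding gene numbered 3, at TCF21 (225 bases), RGPD2 (559 bases), a RANBP2-like gene, and ATP10A (880 bases), a phospholipid flippase gene. Without the spacer regions the share was 11.5% against 7.54% (exact binomial test, adjusted p = 0.570), and with protein-coding genes only it was 4.29% against 4.22% (adjusted p = 0.771).

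Among the 10 promoter regions ranked highest, 5 lay in the spacers and the other 5 were assigned to TCF21, ATP10A, OR4F16, RGPD2 and SCGB1C2. The OR4F16 region, on chromosome 1 at 629145 to 629389, lay 204 bases from the start of MTND1P23, a nuclear copy of a mitochondrial gene, and 70.1% of its 32-base words also occurred in the mitochondrial genome. For the RGPD2 region, on chromosome 2 at 87825129 to 87825347, that share was 23.4%. The start nearest to its centre was that of MTATP8P2, 295 bases away. The SCGB1C2 region, assigned to a secretoglobin gene, had a fold of 4.71 and a −log10 q of 0.70 on chromosome 17 at 117175 to 118111. The start nearest to its centre, 936 bases away, was that of an unnamed gene, and the nearest start of SCGB1C2 was 19927 bases away. The ATP10A region had a fold of 3.56 and a −log10 q of 0.

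Introns held 29 regions (41.4% against 50.3% at random, exact binomial test, adjusted p = 0.304, but 21.4% against 36.6%, adjusted p = 0.031, with protein-coding genes only), intergenic sequence 27 (38.6% against 38.8%, adjusted p = 1) and exons outside promoters 2 (2.86% against 3.40%, adjusted p = 1). With protein-coding genes only, all 18 spacer regions count as intergenic, since their nearest coding start lay 2056833 to 2318111 bases away. That setting was not tested without them. Within 5 kb of a start lay 24 regions (34.3%, exact 95% interval 23.3 to 46.6), against 26.9% of random positions (exact binomial test, p = 0.177). The 35 regions ranked highest by score gave 45.7% against 26.6% (exact binomial test, p = 0.020), and regions outside the spacers gave 23.1% against 26.9% (p = 0.640). The authors' table placed 17 regions inside a gene and 53 outside, and 37 of the 70 lay over 100 kb from the gene it named. That gene was the nearest protein-coding gene for 45 regions.

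Basic helix-loop-helix factors bind E-boxes, hexamers of the form CANNTG, so the regions were searched for them. E-boxes were fewer in the regions than beside them. At least 1 E-box lay in the central 200 bases of 18 regions (25.7%, exact 95% interval 16.0 to 37.6), against 56.4% of flanking windows 2 kb away. The count was higher in the centre for 12 regions and lower for 45 (two-sided exact sign test, adjusted p = 1.2e-04 over 9 patterns). A permutation of windows within regions gave an adjusted p of 0.016. Without the ribosomal DNA spacer regions the shares were 34.6% and 61.5%, and the call held by the sign test (exact, adjusted p = 0.015) but not by permutation (adjusted p = 0.196). In the 35 regions ranked highest by score it did not hold (22.9% against 52.9%, exact sign test, adjusted p = 0.141, permutation, adjusted p = 0.833). In the 27 regions with q under 0.05, chosen after the data were seen, the shares were 7.41% and 57.4% (exact sign test, adjusted p = 0.002). Of those 27, 15 lay in the spacers, and no permutation was recorded for that set. CAGCTG, an E-box form bound by factors of this class, occurred in 3 regions (4.29% against 7.86% of flanks, exact sign test, adjusted p = 0.113, permutation, adjusted p = 0.741). The form CAGATG occurred in 1 (1.43% against 6.43%, exact sign test, adjusted p = 0.064, permutation, adjusted p = 0.401).

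The control hexamer CTGCAG, made of the same bases as CAGCTG, was also rarer in the regions, at 1.43% against 10.0% (sign test, adjusted p = 0.008; permutation, adjusted p = 0.192). GATA sites occurred in 20% against 29.3% (exact sign test, adjusted p = 0.162, permutation, adjusted p = 0.959). The site of NR5A1, the steroidogenic nuclear receptor, was found in 0 of 70 regions, which allows a share of up to 4.29% (one-sided limit; the two-sided exact 95% interval reaches 5.13%), and in 0% of flanks (exact sign test and permutation, adjusted p = 1 for both). In the 30 regions with at most 50% of their bases in tandem repeats with periods up to 60 bases, 50% had an E-box against 56.7% of flanks (permutation, adjusted p = 1). With periods up to 200 bases 26 such regions were left, and 53.8% had an E-box against 53.8% of flanks (permutation, adjusted p = 0.906). In the ribosomal DNA spacers, the regions held 2 E-boxes in 17047 bases, or 0.117 per kb, against 3.80 per kb in the rest of the spacer.

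**Figure D3:**
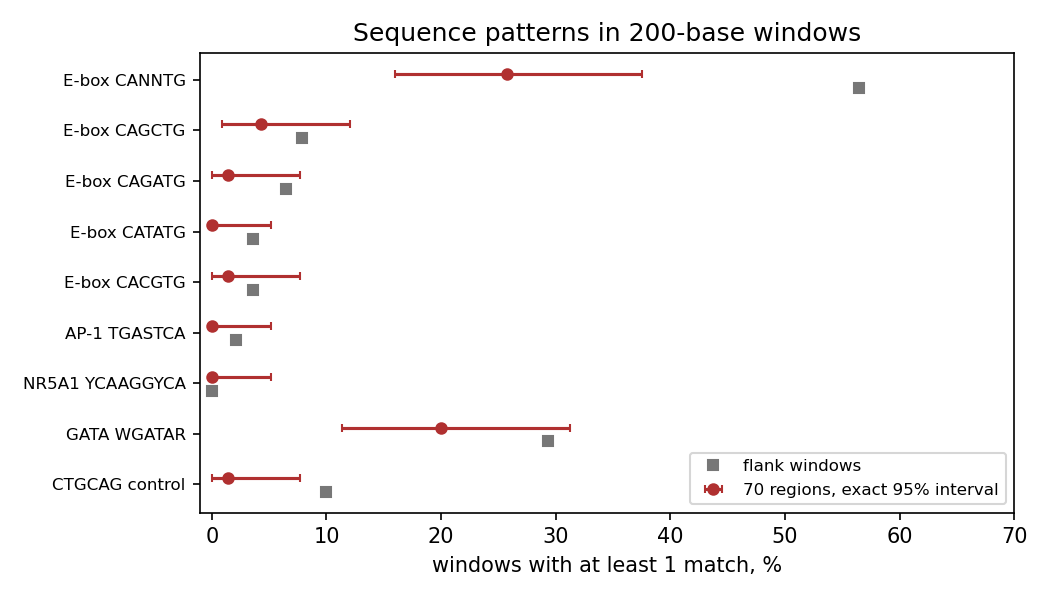
Percent of 200-base windows with at least 1 match (horizontal axis) to each of 9 sequence patterns (vertical axis), for the centres of the 70 regions (circles with exact 95% intervals) and for windows 2 kb to each side (squares). CANNTG was found in 25.7% of regions and 56.4% of flanking windows.

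Gene lists that fit the adrenal cortex were then compared with the genes nearest to the regions. No steroidogenic gene, such as STAR, CYP11A1 or CYP17A1, was the nearest gene of a region (0 of 21 list members), and neither was any of the 25 adrenal and gonadal identity genes, NR5A1 among them. The lists of adrenocortical carcinoma drivers, mitosis genes, epithelial-mesenchymal transition and matrix genes, and Wnt signalling genes, with 24, 20, 28 and 33 members, also had 0 regions. Of the 20 basic helix-loop-helix genes, TCF21 itself had a region (1 region, 0.0273 expected, exact binomial test, p = 0.027, adjusted p = 0.242 over 9 lists). The 34 ribosomal protein genes kept as a control had 0 regions, and the control list of 30 long genes had 1, in CNTNAP2 (0.371 expected, exact binomial test, adjusted p = 1).

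None of the 9 lists passed the threshold (0 lists at an adjusted p under 0.05, 1 list at an unadjusted p under 0.05). Between 0.007 and 0.371 regions were expected per list, so 0 regions was the likeliest count for each list by chance alone. With the 27 regions of q under 0.05, chosen after the data were seen, the basic helix-loop-helix list passed through the TCF21 region alone (exact binomial test, adjusted p = 0.035). That region is reported as uncertain below, because it may hold plasmid reads.

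The last comparison concerned the TCF21 gene, since the transfected plasmid is named for POD1, although its insert is not given in the sources used here. A single region lay there, on chromosome 6 at 133889270 to 133889852, with a score of 1000, a fold of 5.25, a −log10 p of 6.95 and a −log10 q of 1.49. It covered 578 bases of exon 1 and ended 5 bases past the end of that exon. All 450 coding bases of exon 1 lay inside it and made up 77.2% of its length. It began 128 bases before the coding start, and its summit at 133889376, in the 5′ untranslated region, was 22 bases before the coding start. The summit lay inside a run of 22 pyrimidines at 133889360 to 133889381. The region held 2 E-boxes and 0 copies of CAGCTG. If the plasmid held TCF21 coding sequence, its reads cannot be separated from genomic reads in the merged table, so the region is reported as uncertain.

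**Figure D4:**
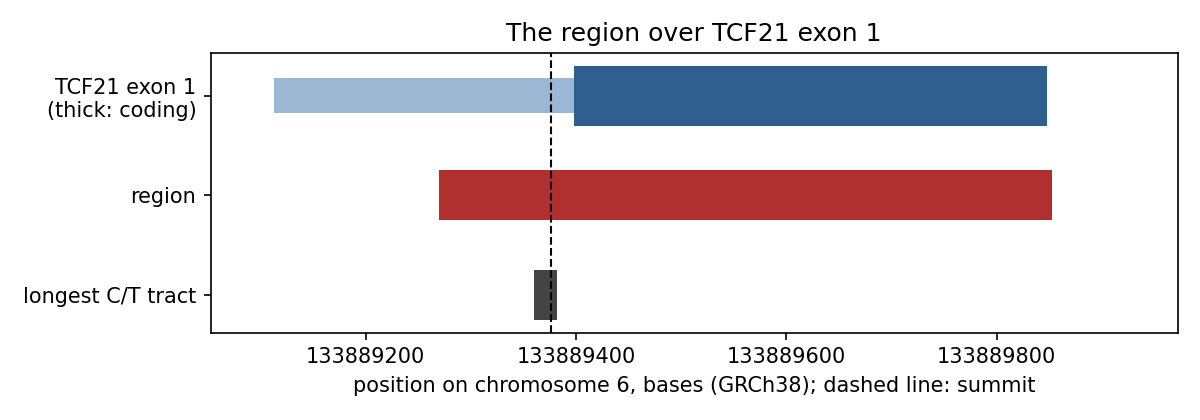
Map of TCF21 exon 1 (top; thick part coding), the region (middle) and its longest C/T tract (bottom) by position on chromosome 6 in bases, with the summit as a dashed line. The region ends 5 bases past the exon, and the summit lies in the tract, 22 bases before the coding start.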

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

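The sets without spacer regions, with q under 0.05, at most 50% tandem repeat, and the within-region permutation were chosen after the data were seen. No paired analysis was possible because the merged table holds no values per library, and for the same reason no replicate could be left out and depth sets no stated limit. Of 192 alternative values, 139 kept their direction and their side of the threshold. Without the spacer regions, chromosome 21 held 1 region, the promoter share was 11.5% and the share within 5 kb of a start turned from above to below random at 23.1%. There the exon share (3.85%) and the intergenic share (42.3%) turned to above random. The spacer regions themselves made these differences, by construction. They also weigh on the settings below, with 10 of the 20 regions ranked highest and 15 of the 27 with q under 0.05. With protein-coding genes only, all 18 count as intergenic, at least 2056833 bases from a coding start. Class and distance shares without them were not tested within those settings, except within 1 kb of a start. That window repeats the promoter comparison, which without the spacer regions gave 11.5% against 7.54% (exact binomial test, unadjusted p = 0.285). The causes of the remaining differences were not tested. With protein-coding genes only, the promoter share was 4.29% and no longer passed, the share within 5 kb turned to 8.57% against 15%, exons turned to 2.86% against 2.40%, and intergenic sequence turned to 71.4% against 56.8% (exact binomial test, adjusted p = 0.031), while introns passed at 21.4% against 36.6% (adjusted p = 0.031). With a promoter window of 3 kb the promoter share was 30.0% against 18.4% (exact binomial test, adjusted p = 0.077), and the exon share, 2.86%, turned to above 2.26%. The distance result passed its threshold in the 35 regions ranked highest by score (45.7%), within 1 kb (17.1%) and with q under 0.05 (48.1%). In that last set introns turned to 51.9% against 48.5%, and 1 gene list passed, through the TCF21 region alone, which is reported as uncertain. The E-box share stayed below its background in all settings but 1, the regions at most 50% tandem repeat with periods up to 200 bases, where both were 53.8% (permutation, adjusted p = 0.906). It no longer passed in those 35 regions (22.9% against 52.9%, exact sign test, adjusted p = 0.141, permutation, adjusted p = 0.833), by permutation without the spacer regions (34.6%, adjusted p = 0.196) or in regions at most 50% tandem repeat with periods up to 60 bases (50%, adjusted p = 1). CAGATG turned to 2.86% against 1.43% in those 35 regions, and CAGCTG to 10.0% against 8.33% and 7.69% against 3.85% in the sets of periods up to 60 and 200 bases. None of these turns passed the threshold by permutation. With periods up to 60 bases the CAGCTG share rested on 3 of 30 regions, and the count was higher in the centre for 3 regions and lower for 5. Against GC-matched windows the biased sign test called 7 further patterns, of which the permutation called 1, CAGATG (adjusted p = 0.019). Over whole regions the sign test called 5 further patterns as rarer (CAGCTG, CAGATG, CATATG, CACGTG and AP-1), and the permutation called 2 of them, CAGATG (adjusted p = 0.003) and AP-1 (adjusted p = 0.044), as well as the control CTGCAG (0% against 10.0%, adjusted p = 0.036).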

Other observations

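The E-box sign test over all regions and the count of regions over TCF21 exons were planned. The E-box tests without the spacer regions, within the spacers, by permutation and in regions at most 50% tandem repeat were chosen only after the regions had been looked at. So were the tests of copies and tandem repeats and the comparison of the TCF21 region with the exon ends.

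Several regions assigned to unrelated genes shared sequence. The regions assigned to PRDM7 on chromosome 16 and CACNA1B on chromosome 9, near the ends of their chromosomes, shared 237 words of 32 bases, 68.1% of those of the smaller set, and PRDM7 shared 144 (70.2%) with SCGB1C2 on chromosome 17. Self-matches in these 3 regions peaked at shifts of 189 bases (95.4% of bases), 63 bases (86.1%) and 126 bases (98.2%). PRR20E on chromosome 13 and LCE5A on chromosome 1 shared 128 words (78.0%). In all, 23 pairs of regions outside the spacers shared at least 1 word.

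Regions in the ribosomal DNA spacers. Of the 17 regions that followed a 45S gene, 13 had a counterpart at a similar distance in another spacer. Binding at E-boxes of the spacer was argued against, because E-boxes per kb stood at 0.0309 times the level of the rest of the spacer. Tandem repeats stay open as a technical explanation, since the share of bases in them was 7.66 times that of the rest of the spacer (permutation by rotation, one-sided p = 2.0e-04). Whether reads shared between rDNA copies contributed could not be decided, because a median of 100% of the words in these regions occurred 2 or more times in the reference, but so did 94.9% to 100% of the words of the 45S genes, which none of the 18 regions overlapped. Binding without an E-box was not tested, nor was a difference in rDNA copy number or shearing between ChIP and input.

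Regions outside the spacers. Tandem repeats made up most of the sequence in 24 of 52 regions (46.2%) against 1.15% of random windows, an odds ratio of 73.4. With over 90% of bases required the share was 28.8% against 0.385%, and with periods up to 200 bases it was 53.8%. Most words were multi-copy in 75.0% against 15.2%, an odds ratio of 16.7 (32.7% against 8.17% with over 90% of words required), and in 70.8% of the 24 regions at most 50% tandem repeat with periods up to 200 bases against 14.8% of such windows, so both may account for part of the list. How reads were placed in such sequence is not known here and was not tested. Against E-box binding as the source of the set as a whole, 26.1% of the regions that differed from their flanks had more E-boxes in the centre, below the 42.0% that permutation within regions gave (permutation p = 0.022, for the E-box alone; the summed count gave an adjusted p of 0.196 over 9 patterns). Outside the spacers the control CTGCAG was also rarer, at 1.92% against 9.62% of flanks (exact sign test, adjusted p = 0.053, permutation, adjusted p = 0.510). A shortfall in the centre was thus not seen for E-boxes alone, which limits this argument. E-box binding stays open in regions with less tandem repeat. There the share with more E-boxes in the centre was 36% against 43.8% by permutation (permutation p = 0.462) in the 28 regions at most 50% tandem repeat with periods up to 60 bases. It was 38.1% against 44.2% (permutation p = 0.627) in the 24 left with periods up to 200 bases.

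The region over TCF21 exon 1. Of the 27 regions with q under 0.05, TCF21 was the 1 region that was neither mostly multi-copy nor mostly tandem repeat. The other regions of that kind, at MTERF1, DPP10, TEX51, OR4C45, CFDP1 and NHSL1, had a q of 0.05 or more. Plasmid reads may explain the TCF21 region, since it ended 5 bases past the end of exon 1 and held the whole coding part of that exon, but the insert is not given in the sources used here, and exon 2, whose 87 coding bases are fewer than the 163 of the narrowest region, had no region. The TCF21 region began 128 bases before the coding start and its summit lay 22 bases before it, outside coding sequence. Both distances are below the average library fragment length of 250 bases, and the ends of the insert are not known here. These distances therefore cannot decide for or against plasmid reads. Per the labels' protocols, the input cells were transfected as well, so plasmid reads could also occur in the input. A repeat at the summit may also contribute, since 65 of the 100 bases around it lay in tandem repeats. Binding of TCF21 at its own gene stays open and untested.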
